A study of Danio rerio with 6 samples.

How the data were processed

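Zebrafish zygote RNA recovered by immunoprecipitation of Tdrd6a and input RNA were analysed, with 3 libraries in each of the 2 groups. Per the labels' protocols, RNA was extracted with Trizol, libraries were made with the Ovation RNA-seq System V2 kit of NuGEN, and 50 bp single-end reads were sequenced on an Illumina HiSeq. The submitters' processing notes name TopHat, DESeq and the Zv9 assembly, without versions; the counting tool, annotation and use of strand are not given in the sources used here. Without known strand use, reads of overlapping sense and antisense genes cannot be told apart.

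The deposited values are a read-count signal, given by the authors as normalized counts with 1 decimal for 21051 genes. Low values of each library were whole multiples of a constant, the value of 1 read, which ranged from 0.682 to 3.76 normalized counts. Dividing by it recovered whole reads. At least 99.98% of the values above 0 in each library lay within 0.06 normalized counts of a whole multiple of it. The recovered totals were 10481205, 16048024 and 19804774 reads for input replicates 1, 2 and 3 and 22466764, 4031863 and 9701595 for IP replicates 1, 2 and 3. Counting precision is lowest in IP replicate 2. Reads carry no molecular identifiers here, so counting intervals cover counting error only.

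Group and replicate number were taken from the sample labels. The plan fixed before the data were examined was edgeR on raw counts. Because the deposited values are normalized, the test used was limma 3.58.1 (moderated by an abundance trend, robust) on log2(normalized count + 4) in R 4.3.3, with group as the only term, two-sided, and Benjamini-Hochberg adjustment over the genes tested. The pseudocount of 4, about the value of 1 read in the shallowest library, and the minimum mean normalized count of 10, which left 13265 genes, were chosen after the file was seen. Fold changes are on the log2(value + pseudocount) scale, which understates the change of low genes. A gene was called at an adjusted p under 0.05. edgeR 4.0.16, DESeq2 1.42.0 and limma voom were run on the recovered reads as alternatives; edgeR called 867 genes there (603 higher, 264 lower).

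Gene lists were fixed before the data were examined, 20 in number, of which 19 had at least 3 tested members. They were tested with camera, with a preset inter-gene correlation of 0.01, on the same values, with Benjamini-Hochberg adjustment over the 19 lists. Of the lists, 6 were called, and 0 with an estimated correlation. Of 13 germ plasm names 11 were matched; h1m and kop were not. Genes were matched by the symbol in the file, then by RefSeq synonyms of clone names (assembly GRCz12tu) and then by the table of gene identifiers and symbols, in which 16425 of the 21051 identifiers were found. The named genes were fixed by rule: tdrd6, all tested germ plasm members, the 10 largest increases and the 10 largest decreases among called genes with separated groups, a mean of at least 50 reads and a gene name, and the 3 members of smallest p in each other list. Some genes that the rule takes are not reported here. The rule passed over 4 unnamed genes on the higher side and 15 on the lower. Shares of reads were compared by two-sided exact permutation tests, whose smallest possible p is 0.1.

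Libraries with the same replicate number deviated together from their group means, with correlations of 0.294, 0.305 and 0.301 for replicates 1, 2 and 3 across genes, against -0.0704 to -0.210 for libraries with different numbers. Deviations within a group cancel out, so the negative values for different numbers partly follow from the positive values for the same numbers. The numbers in the labels may thus pair the libraries. The fit reported did not use this pairing, and a fit with replicate number as a block was run as an alternative. No pair of libraries within a group agreed within sampling noise, so all 6 were counted.

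The fit was tested on simulated reads over 12638 genes, with the input means, raised to a minimum for low genes, and the real depths. Genes were drawn independently, with a spread set by the abundance trend alone and without a replicate effect. The fit recovered 6.38% of genes changed 2-fold, 63.8% of those changed 4-fold, 87.5% of those changed 8-fold and 100% of those changed 32-fold. There were 3 false calls among 12448 unchanged genes, and 0 of 20 unchanged lists were called. The unchanged lists had no correlation between genes, so the simulation cannot show how often camera calls lists falsely in these data. The rates for genes hold for that simpler setting only. Alternatives covered the scaling, the abundance filter, the pseudocount, the test, the replicate block, a test against a fold of 1.5 and leaving out each library. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 was used for the recovery of reads, the shares and the figures. No genome or annotation of the Zv9 assembly was used here, so corrections for GC content and transcript length were not made.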

Results

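RNA immunoprecipitation followed by sequencing (RIP-seq) was applied to zebrafish zygotes. RNA recovered with Tdrd6a, a Tudor domain protein of the germ plasm (the maternal material inherited by primordial germ cells), was compared with input RNA. There were 3 Tdrd6a immunoprecipitate (IP) libraries and 3 input libraries. The table held 21051 genes, of which 13265 reached the abundance minimum and were tested. The input libraries held 10481205, 16048024 and 19804774 reads in replicates 1, 2 and 3, and the IP libraries held 22466764, 4031863 and 9701595. IP replicate 2 was thus the shallowest library, in which 1 read was worth 3.76 normalized counts. The labels name the source as zygotes. The design text of the series speaks of ovary tissue or RIP, and the labels of the samples were followed. Nothing in the labels says whether replicates came from separate clutches, so p-values measure the spread between these libraries, which may be technical. No library of a mock or unrelated antibody was analysed here, so IP was compared with input alone.

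The comparison asked which maternal transcripts were over- or under-represented in the Tdrd6a IP. Germ plasm transcripts were the most enriched group. All 11 measured members of the germ plasm list were higher in IP than in input, with a median log2 fold change of 5.48, a 44.6-fold difference. Of these members, 10 stood among the 20 largest positive log2 fold changes of all genes tested and the last, camk2g1, ranked 49. Over all genes, 838 differed at an adjusted p under 0.05, of which 591 were higher and 247 lower in IP, and 590 of the higher and 240 of the lower genes differed by at least 2-fold. The higher side held the larger changes: 109 genes were at least 8-fold higher, against 3 at least 8-fold lower.

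**Figure D1:**
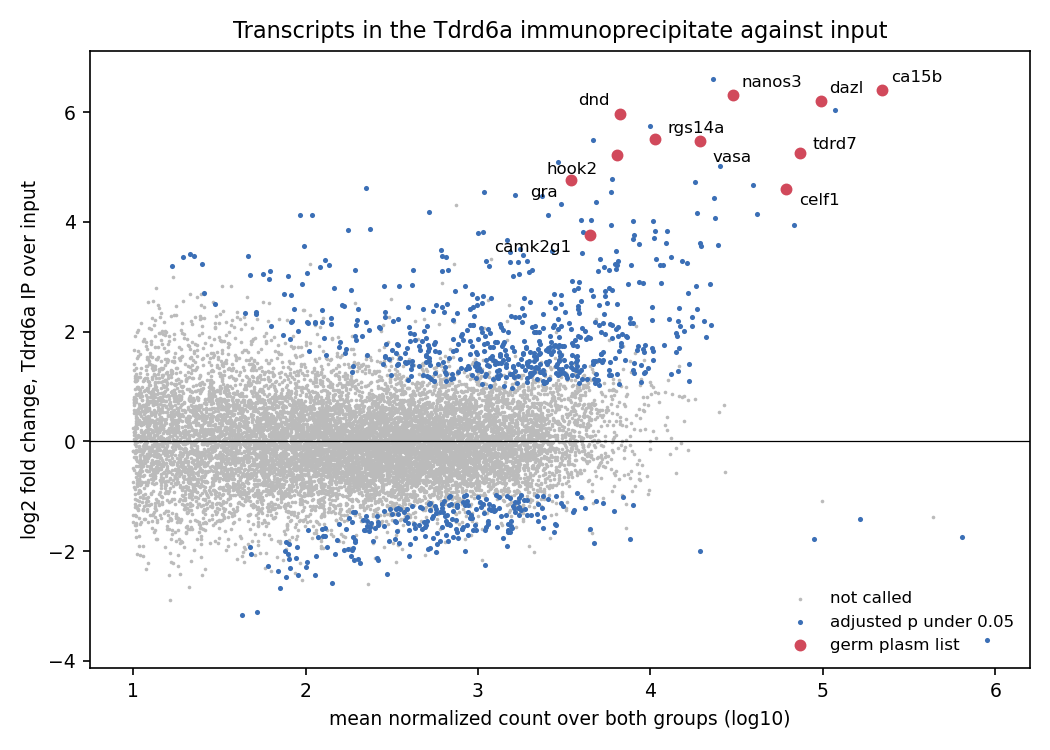
Log2 fold change of IP over input (vertical axis) against the mean normalized count over both groups (horizontal axis, log10), with a point for each of the 13265 genes tested. Blue points are the 838 genes called, grey points were not called, and the 11 red points are the germ plasm list, between 3.76 and 6.40 on the log2 scale.

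Among single germ plasm transcripts, ca15b (ENSDARG00000040510) had a mean normalized count of 4842 ± 1377 (SD, n = 3) in input and 438321 ± 219499 in IP, a log2 fold change of 6.40 ± 0.43 (SE, adjusted p = 0.000103). The transcript of nanos3, a translational regulator needed for germ cell survival, differed by 6.31 ± 0.63 (adjusted p = 0.00186). That of dazl, an RNA-binding protein of germ cells, differed by 6.20 ± 0.56 (adjusted p = 0.000612). The transcript of dnd, which encodes the RNA-binding protein Dead end, rose from 183 ± 41.0 to 13112 ± 8379 normalized counts (log2 fold change 5.97 ± 0.41, adjusted p = 0.000111). The germ cell helicase gene vasa differed by 5.48 ± 0.59 (adjusted p = 0.00207), and tdrd7, which encodes another Tudor domain protein, by 5.26 ± 0.44 (adjusted p = 0.000199). The remaining 5 members, rgs14a (5.52), hook2 (5.22), gra (4.76), celf1 (4.61) and camk2g1 (3.76), were called too, rgs14a with the largest adjusted p of the list, 0.00926. The list held 11 calls adjusted over the list alone and 11 over all genes, and its camera adjusted p was 2.2e-22 (adjusted p = 0.31 with an estimated correlation). The size of the enrichment differed between IP libraries, with a median of 42.3-fold over the input mean in replicate 1, 102-fold in replicate 2 and 17.3-fold in replicate 3. Without IP replicate 3 the estimates were 7.03 for nanos3, 6.90 for dazl, 6.34 for rgs14a, 6.22 for vasa and 5.22 for celf1, and without IP replicate 2 they were 5.57 for nanos3, 4.88 for vasa and 4.55 for rgs14a. Without input replicate 3, rgs14a missed the threshold (adjusted p = 0.0532).

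**Figure D2:**
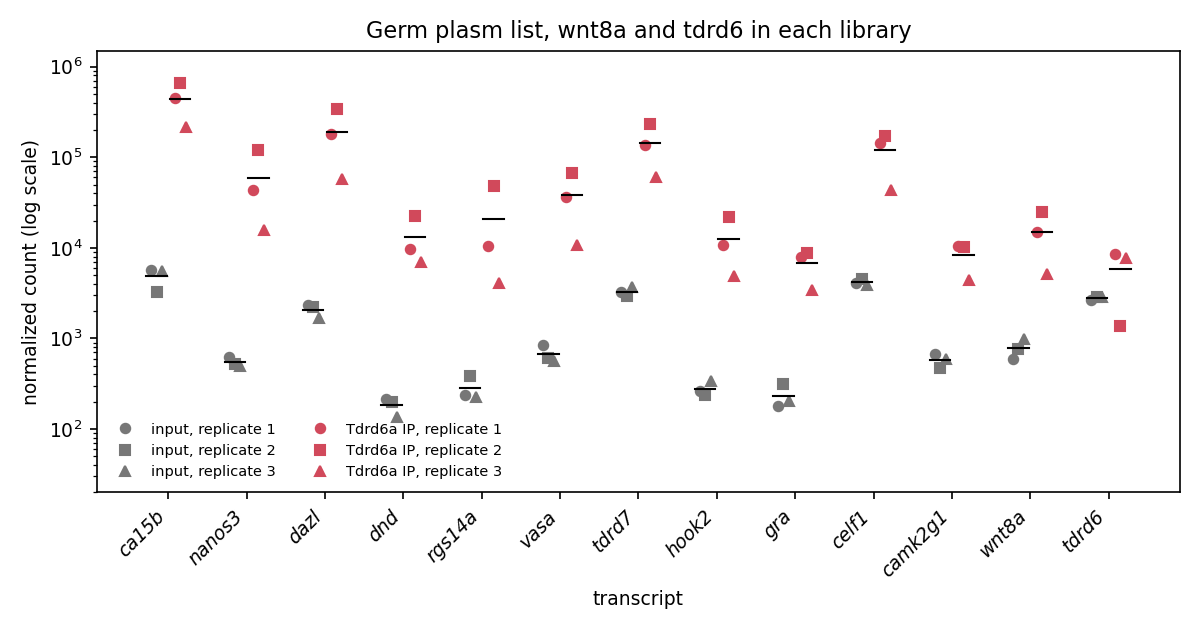
Normalized counts (log scale) of the 11 germ plasm transcripts, wnt8a and tdrd6 in the 3 input libraries (grey) and the 3 IP libraries (red), with horizontal bars at group means. In the 11 germ plasm transcripts and in wnt8a all 3 IP libraries lie above all 3 input libraries, while tdrd6 has IP replicate 2 at 1384, below the inputs.

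Outside that list, the largest increases among genes with a name were those of akap9 (5.75 ± 0.48, adjusted p = 0.00031), which encodes a centrosomal and Golgi scaffold protein, and CEP152 (5.01 ± 0.39, adjusted p = 0.000111), a centriole duplication factor. The transcript of the precipitated protein itself, tdrd6 (ENSDARG00000070052), was not called. It had 2794 ± 99.5 normalized counts in input and 8445, 1384 and 7708 in IP replicates 1, 2 and 3, a log2 fold change of 0.68 ± 0.64 (adjusted p = 0.607). Without IP replicate 2 the difference was 1.53 with an adjusted p of 0.00094.

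Transcripts with a vegetal location in the egg or early embryo were also enriched. Of the 5 measured, 4 were higher over all genes and 4 when adjusted over the list alone, with a median log2 fold change of 2.12. The transcript of the maternal Wnt ligand wnt8a rose 16.2-fold (4.02 ± 0.52, adjusted p = 0.00357), that of the dorsal determinant huluwa (hwa) 5.61-fold (2.49 ± 0.36, adjusted p = 0.00323) and that of grip2a 4.35-fold (2.12 ± 0.37, adjusted p = 0.00996). Also called was sybu, the gene of the kinesin linker Syntabulin (1.52 ± 0.28, adjusted p = 0.0108, chosen after its values were seen), while magoh was at -0.34. The list's camera adjusted p was 0.00021 (adjusted p = 0.31 with an estimated correlation). Leaving out input replicate 1 or input replicate 3 left 2 members called, sybu was not called when any 1 input library was left out, and wnt8a was at 4.66 without IP replicate 3.

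Ribosomal protein transcripts formed the main group on the lower side. Of 84 cytosolic ribosomal protein genes measured, 30 were lower, 0 higher and 54 not called, with 59 lower and 0 higher when adjusted over the list alone. Their median log2 fold change was -1.20, and 81 of the 84 estimates lay below 0. The transcript of rps25 fell from 503 ± 145 normalized counts in input to 89.1 ± 5.39 in IP (-2.41 ± 0.34, adjusted p = 0.00299), and those of rpl39 (-2.16) and rps14 (-2.00) were also lower. The camera adjusted p was 7.5e-26 (adjusted p = 0.31 with an estimated correlation). The count of lower members was 2, 6 and 3 without input replicates 1, 2 and 3, and 4, 48 and 17 without IP replicates 1, 2 and 3. It was 15 with no filter beyond 1 read, 47 with DESeq2 and 2 against a fold of 1.5. The estimate of rpl39 was -2.78 without IP replicate 2, and rpl39 was not called with no filter beyond 1 read (adjusted p = 0.0749) or with edgeR (adjusted p = 0.0507).

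Transcripts encoded in mitochondrial DNA were lower as well. All 13 protein genes had estimates below 0, with a median log2 fold change of -1.65. Over all genes 5 were called lower and 8 were not called, and 12 were lower when adjusted over the list alone. Examples were mt-nd4 (-1.85 ± 0.35, adjusted p = 0.0131), mt-nd3 (-1.76 ± 0.34, adjusted p = 0.0143) and mt-nd5 (-1.59 ± 0.27, adjusted p = 0.00738), subunits of respiratory complex I. With replicate number as a block 13 were lower, with DESeq2 11, with no filter beyond 1 read 3 and against a fold of 1.5 0. Camera gave an adjusted p of 7.0e-10 (adjusted p = 0.42 with an estimated correlation), while fry, which tests the list on its own, gave 0.0941, so the list was not called with it. The number called lower was 0 without input replicate 2 or input replicate 3, 1 without IP replicate 1 and 11 without IP replicate 2. As a share of all reads, these genes took 0.738 ± 0.373% (SD, n = 3) in input and 0.199 ± 0.0876% in IP, where every IP library was below every input library (two-sided exact permutation p = 0.1, the smallest that 3 libraries against 3 allow).

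The list of 73 translation factor transcripts lay lower to a lesser degree, with a median log2 fold change of -0.42. Of the estimates 48 lay below 0 and 25 above. Of these genes 2 were higher, 4 lower and 67 not called, and adjusted over the list alone 3 were higher and 8 lower. With the replicate block 9 were lower, and with DESeq2 4 were higher and 10 lower. The elongation factor gene eef1a1l1 (-1.16 ± 0.26, adjusted p = 0.0248) and eif4h (-1.45 ± 0.33, adjusted p = 0.0255) were lower, while eif6, a factor of ribosome assembly, was higher (1.14 ± 0.27, adjusted p = 0.0297). No member was higher with library size only, where eif6 had an adjusted p of 0.0814, and with no filter beyond 1 read 0 were higher and 1 lower, with adjusted p of 0.0553 for eif6 and 0.0519 for eif4h. The call of eef1a1l1 was lost with edgeR and the block (adjusted p = 0.0518), and against a fold of 1.5 there were 0 calls. The camera adjusted p was 0.0046 (adjusted p = 0.31 with an estimated correlation). No member was called when any input library was left out, without IP replicate 1 there were 0 higher and 1 lower, and without IP replicate 2 there were 6 higher and 8 lower.

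The direction of motor protein transcripts (kinesins, dyneins and myosins) differed between IP libraries, with list medians over the input mean of 0.99, -0.12 and 0.47 on the log2 scale in replicates 1, 2 and 3. Of 72 genes 6 were higher, 1 lower and 65 not called, with 8 higher and 1 lower adjusted over the list alone, and the median log2 fold change was 0.47. The myosin genes myo18ab (2.87 ± 0.34, adjusted p = 0.00107) and myo9ab (1.59 ± 0.31, adjusted p = 0.0143) were higher, and a dynein light chain gene, dynll2b (ENSDARG00000005172), was lower (-1.81 ± 0.37, adjusted p = 0.0177). The camera adjusted p was 0.013 (adjusted p = 0.91 with an estimated correlation), and it was 0.069 among genes with a CPM of at least 5 in 3 libraries and 0.27 without IP replicate 1, while fry gave 0.449. The count of higher members was 3 with no filter beyond 1 read, 12 with DESeq2 (3 lower), 9 with the replicate block and 1 against a fold of 1.5. It was 1, 2 and 1 without input replicates 1, 2 and 3, 2 without IP replicate 1 and 21 without IP replicate 2, and dynll2b was not called when any 1 input library or IP replicate 1 was left out.

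Transcripts of the piRNA pathway and germ granule proteins were not called as a list against other genes (camera adjusted p = 0.31), while fry, which tests the list on its own, gave an adjusted p of 0.0207 on the higher side. Of 21 genes 3 were higher and 1 lower over all genes, and 4 higher and 1 lower adjusted over the list alone. Against a fold of 1.5 there were 0 calls. The transcripts of tdrkh, a Tudor domain partner of Piwi proteins (1.61 ± 0.29, adjusted p = 0.0109), and of rbpms2a, an RNA-binding protein of the Balbiani body (1.65 ± 0.35, adjusted p = 0.0199), were higher, and that of gtsf1 was lower (-1.54 ± 0.25, adjusted p = 0.00602). For the genes of the germ plasm organiser Bucky ball, buc, and of the Piwi proteins Ziwi (piwil1) and Zili (piwil2), chosen after their values were seen, the estimates were -0.55 ± 0.30, -0.28 ± 0.32 and 0.25 ± 0.29, with adjusted p of 0.326, 0.681 and 0.679. The higher count was 0 without input replicate 1 or 3, 1 without input replicate 2 or IP replicate 1 and 6, with 2 lower, without IP replicate 2.

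**Figure D3:**
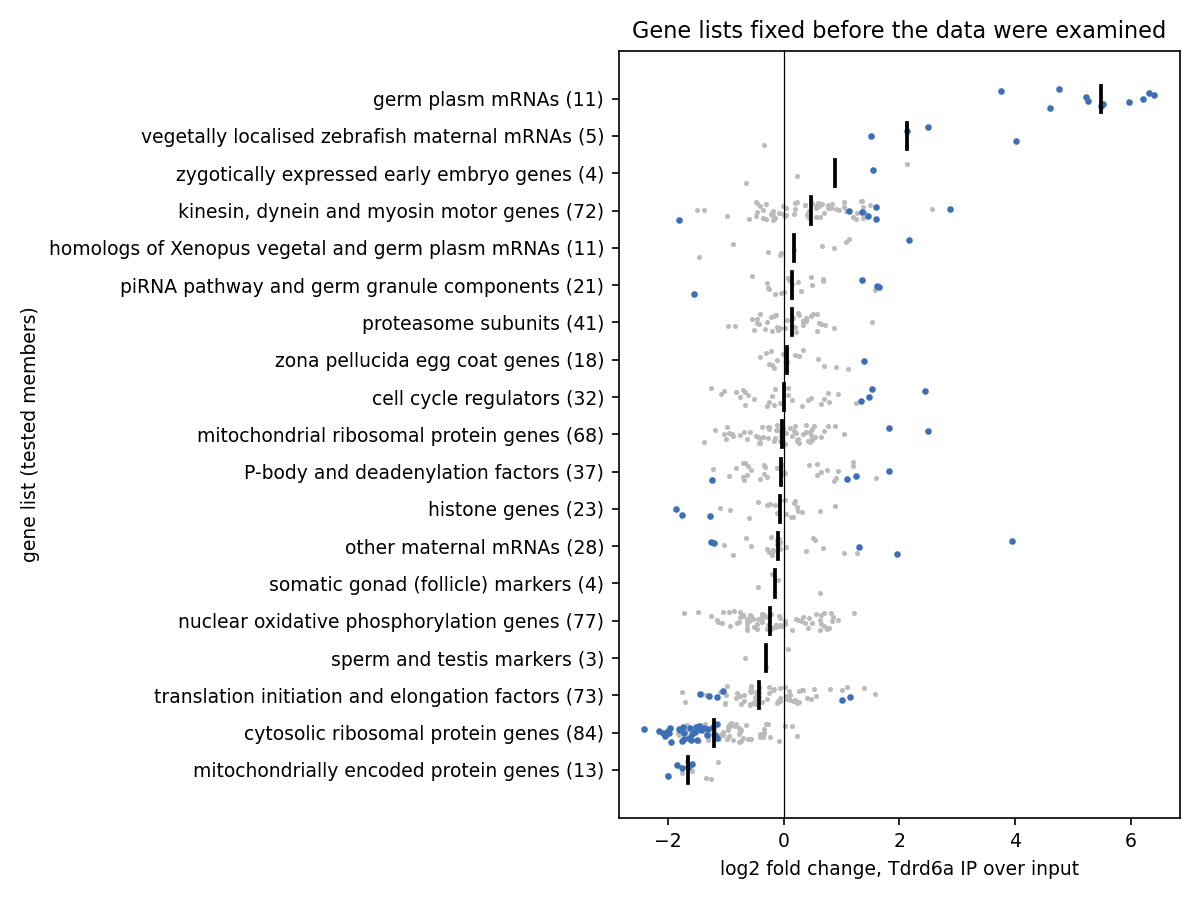
Log2 fold change of IP over input (horizontal axis) for each measured member of the 19 gene lists tested (vertical axis, number of members in parentheses). Blue points are genes called over all genes tested, grey points were not called and black bars are list medians, from 5.48 for germ plasm mRNAs to -1.65 for mitochondrially encoded protein genes.

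Among other maternal transcripts, 3 of 28 were higher, 2 lower and 23 not called (4 higher and 4 lower adjusted over the list alone). The transcript of slbp2, the oocyte form of the histone stem-loop binding protein, rose 15.5-fold (3.95 ± 0.45, adjusted p = 0.00107), eomesa rose 3.89-fold (1.96 ± 0.35, adjusted p = 0.0101) and cth1 was lower (-1.26 ± 0.26, adjusted p = 0.0193). Of 32 cell cycle regulators 4 were higher, 0 lower and 28 not called (6 higher and 4 lower adjusted over the list alone), among them espl1, the gene of separase (2.44 ± 0.34, adjusted p = 0.00283), and the checkpoint and chromosomal passenger genes bub3 (1.53) and aurkb (1.48). Of 37 P-body and deadenylation factors 3 were higher, 1 lower and 33 not called (8 higher and 2 lower adjusted over the list alone), with the deadenylase gene cnot7 at 1.81 ± 0.35 (adjusted p = 0.0148) and lsm14aa at -1.24 ± 0.25 (adjusted p = 0.0179). The deadenylase gene cnot6 (2.14-fold higher, adjusted p = 0.0365) was not called with the replicate block (adjusted p = 0.0699), library size only (adjusted p = 0.0522), edgeR (adjusted p = 0.061) or edgeR with the block (adjusted p = 0.115). With that block 5 genes of the maternal list and 5 of the P-body list were higher. With DESeq2 the P-body list had 7 higher and 1 lower. Against a fold of 1.5 the maternal and cell cycle lists had 1 higher each, and the P-body list had 0 calls. With no filter beyond 1 read the maternal, cell cycle and P-body lists had 2 higher each, and aurkb was not called (adjusted p = 0.0695). Of 11 homologs of Xenopus vegetal and germ plasm transcripts 1 was higher, trim36 (2.17 ± 0.39, adjusted p = 0.0109), with 2 higher and 1 lower adjusted over the list alone. None of these 4 lists was called as a group, with camera adjusted p of 0.93, 0.77, 0.93 and 0.73 in that order. With any 1 input library left out, at most 1 member of the maternal and cell cycle lists and 0 of the P-body and Xenopus lists were called; in the order given, the higher counts were 2, 1, 1 and 1 without IP replicate 1, 3, 7, 8 and 2 without IP replicate 2 and 2, 6, 4 and 2 without IP replicate 3. The lower counts of these lists were 4, 1, 3 and 1 without IP replicate 2, against 2, 0, 1 and 0 with all libraries, and the maternal list had 1 without IP replicate 1 or 3.

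Of 23 histone genes 3 were lower, 0 higher and 20 not called (4 lower and 0 higher adjusted over the list alone), including both copies named h3f3b.1, which encode histone H3.3 (-1.86 and -1.76), and h2afvb (-1.28). With no filter beyond 1 read, h2afvb (adjusted p = 0.0593) and 1 copy of h3f3b.1 (adjusted p = 0.0547) were not called. Whether reads were shared between the h3f3b.1 copies was not tested. The camera adjusted p of the histone list was 0.13, and it was 0.041 without input replicate 2 and 0.0076 without IP replicate 2. Of 68 mitochondrial ribosomal protein genes, mrps2 (2.49 ± 0.50, adjusted p = 0.0195) and mrps30 (1.83 ± 0.36, adjusted p = 0.0158) were higher, the only 2 called there, both over all genes and adjusted over the list alone, and mrps2 was at 3.11 without IP replicate 3. Of 77 nuclear oxidative phosphorylation genes, limma called 0 over all genes and 0 adjusted over the list alone, with 9 at an unadjusted p under 0.05; on recovered reads edgeR called 0, voom 0, or 1 with quality weights, and DESeq2 3. Camera gave that list an adjusted p of 0.25, or 0.012 without IP replicate 2, where 1 member was called lower. Of 41 proteasome subunit genes limma called 0 on either scale, with 4 at an unadjusted p under 0.05, and edgeR, voom and DESeq2 called 0. Of 18 egg coat (zona pellucida) genes zp3f.2 was higher (1.38 ± 0.31, adjusted p = 0.0255), the only 1 called over all genes or adjusted over the list alone, and it was not called with library size only (adjusted p = 0.0666) or with no filter beyond 1 read (adjusted p = 0.0508). The camera adjusted p was 0.77 for mitochondrial ribosomal proteins, 0.77 for the proteasome and 0.56 for the egg coat. Leaving out any input library or IP replicate 1 left 0 genes of the mitochondrial ribosomal, egg coat and zygotic lists called, and at most 1 histone gene; zp3f.2 was also lost without IP replicate 3, where 2 zygotic genes were higher.

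Markers of other cells and stages were few. Of 4 measured zygotic genes cxcr4b was higher (1.54 ± 0.38, adjusted p = 0.0372), and 2 were higher adjusted over the list alone. It was not called with library size only (adjusted p = 0.0522) or with no filter beyond 1 read (adjusted p = 0.0782). The transcript of bambia (2.12 ± 0.57) missed the threshold with an adjusted p of 0.0561 and passed it with the replicate block (adjusted p = 0.0043). Of 4 follicle markers and 3 sperm and testis markers limma called 0 over all genes or adjusted over the list alone, edgeR, voom and DESeq2 called 0, and 1 and 0 had an unadjusted p under 0.05, with cyp11a1 at 0.63 and sycp1 at -0.31. Without IP replicate 2 the steroidogenic gene cyp11a1 was called higher (0.83, adjusted p = 0.0443), and no other single library left out gave a call in either list. The camera adjusted p was 0.24 for the zygotic list, 0.93 for the follicle list and 0.65 for the sperm list. Blood and liver markers had fewer than 3 members above the abundance minimum and were not tested.

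Large decreases among named genes outside the groups above included those of cyb5a, the gene of cytochrome b5 (-2.23 ± 0.40, adjusted p = 0.0103), polr2d, an RNA polymerase II subunit gene (-2.17 ± 0.44, adjusted p = 0.0172), commd7 (-2.14), brk1 (-2.09) and pttg1, the gene of securin (-2.08 ± 0.40, adjusted p = 0.0142). A signal recognition particle RNA gene (Metazoa_SRP, ENSDARG00000088254) was at -2.27 ± 0.51 (adjusted p = 0.0246). Each of these 6 genes missed the threshold when input replicate 3 was left out.

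The make-up of the libraries differed in the same comparison. Germ plasm list transcripts took 0.139 ± 0.0146% of reads in input and 7.16 ± 3.8% in IP, and the share of ca15b alone was 76.8 times that in input. The 10 most abundant genes of each library took 30.9 ± 3.69% of reads in input and 14.5 ± 5.79% in IP. The difference was 16.4 percentage points, and the share of a single feature without a name, ENSDARG00000080337, itself fell by 12.0 points. For each of these shares the 3 IP libraries all lay on the same side of the 3 input libraries (two-sided exact permutation p = 0.1, the smallest possible). The 100 most abundant genes took 37.7 ± 3.51% in input and 31.2 ± 8.82% in IP (two-sided exact permutation p = 0.3).

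Scaling by total reads alone put the median of all genes at -0.18 on the log2 scale, from -0.01, and split the calls into 476 higher and 384 lower, against 591 and 247; changes are relative to that shift, under which germ plasm (median 5.29) and ribosomal protein (median -1.39) transcripts kept their signs. Adding the replicate block gave 1392 calls (925 higher and 467 lower), of which 829 were among the 838. The number of calls was 193, 273 and 198 without input replicates 1, 2 and 3, 331 without IP replicate 1, 1732 without IP replicate 2 and 809 without IP replicate 3.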

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

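The alternatives with TMM scaling, pseudocounts of 1 and 10, and edgeR on recovered reads with and without the block were chosen after seeing the data; the others were planned. No called gene named by the rule and no called list changed direction. The 838 calls became 500 with no filter beyond 1 read (101 lower), where 19507 genes were tested, 1392 with the replicate block (925 higher, 467 lower), 1593 with DESeq2 (1042 higher, 551 lower) and 186 against a fold of 1.5 (176 higher, 10 lower). Lower calls, 247 in the fit reported, were 384 with library size only, 418 with voom and quality weights and 449 with edgeR and the block. Leaving out 1 library gave 193 to 1732 calls, 170 to 1185 higher and 10 to 547 lower; the cause was not tested. Of 77 named genes 57 were called, 20 against a fold of 1.5 and 21 to 61 with a library left out. In the other alternatives 11 lost their call at least once, 9 of them with no filter beyond 1 read and 4 with library size only. The germ plasm genes stayed between 3.54 and 7.03 on the log2 scale in 23 alternatives, with 1 loss, rgs14a without input replicate 3 (adjusted p = 0.0532). Beyond the counts given with the results, the replicate block changed no other call of a named gene or list.

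With an estimated correlation 0 lists were called: the adjusted p was 0.309 for germ plasm, vegetal, ribosomal protein and translation factor lists, 0.423 for mitochondrially encoded genes and 0.911 for motors. With fry, which tests a list on its own and not against other genes, it was 0.0158 for germ plasm, 0.0207 for the piRNA pathway list (now past the threshold), 0.0941 for mitochondrially encoded genes and 0.449 for motors. Motors gave 0.0687 with a CPM of at least 5 in 3 libraries. With a library left out, adjusted p ranged from 1.6e-05 to 0.272 for motors, from 0.012 to 0.935 for nuclear oxidative phosphorylation genes and from 0.0076 to 0.514 for histones. The cause was not tested. The difference in the share of the 10 most abundant genes, -16.4 percentage points, was -6.51 for the 100 most abundant (two-sided exact permutation p = 0.3). Corrections for GC content and length, alone and with the block, and the share of all mitochondrial chromosome genes were not run, for want of an annotation here. Depth limits low genes most in IP replicate 2, where 1 read is 3.76 normalized counts.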

Other observations

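All tests in this part were chosen after the main results were seen. The predictions for genomic span, IP replicate 2 as a whole and neighbouring genes were written before those tests were run. The thinned counts in the test of IP replicate 2 were added after. All genes in this part outside the naming rule were chosen after their values were seen. The most enriched feature of all had no gene name: ENSDARG00000087372 rose from 438 ± 161 normalized counts in input to 45459 ± 24261 in IP (log2 fold change 6.61 ± 0.41, SE, limma adjusted p = 0.000103). The feature that took the most reads, ENSDARG00000080337, also without a name, fell from 13.1 ± 2.86% of reads in input to 1.14 ± 0.750% in IP, with a log2 fold change of -3.62 that was -2.98 without IP replicate 2 and was not called without input replicate 3. Besides hook2, akap9 and CEP152, transcripts of the dynein regulator ndel1b (4.68 ± 0.69, adjusted p = 0.00972) and of CCDC88C (4.43 ± 0.34, adjusted p = 0.000111) were among the most enriched, as were larp4b (4.17 ± 0.32) and birc2 (4.63 ± 0.74). The estimates for ndel1b and birc2 changed with the IP library left out: they were 3.94 and 3.87 without IP replicate 2 and 5.52 and 5.48 without IP replicate 3. The miRNA-processing gene dicer1 was higher by 2.27 ± 0.38 (adjusted p = 0.00734). Neither birc2 nor dicer1 was called without input replicate 1 or input replicate 3.

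Several splicing factor transcripts were among the lower genes. Of 72 measured genes of SR proteins, hnRNPs, snRNP proteins and related factors, a set drawn up after its called members were seen, 18 were lower and 2 higher. Lower members included hnrnpa1a (-1.65 ± 0.30, adjusted p = 0.011), hnrnpc (-1.61 ± 0.27, adjusted p = 0.00783), sf3b5 (-1.88 ± 0.34, adjusted p = 0.0101) and srsf1a (-1.58 ± 0.32, adjusted p = 0.0169), and prpf8 was higher (2.19 ± 0.31, adjusted p = 0.00309). The count of lower members was 1, 2 and 0 without input replicates 1, 2 and 3, and 3, 29 and 10 without IP replicates 1, 2 and 3. Whether the family as a whole is under-represented was not decided. The called members prompted the grouping, so a test of all members would be circular. The 52 members that were not called, a set selected by outcome, had a median of -0.54, with 40 below 0. Over 10000 random lists of uncalled genes of like level the median was -0.053 and the lowest value -0.453. Those lists take no account of members varying together in the same libraries, and the set was drawn up after its called members were seen.

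The hypothesis that centrosome and dynein-adaptor transcripts may be enriched as a family was left open. Without the 5 genes that prompted it, 4 of 65 members were higher (6.15%) against 4.41% of other genes (two-sided Fisher's exact test, p = 0.535), 3 were lower and 58 not called, and their median was -0.19. A wider exclusion tried before it, of every member already seen among the called genes, left 2 of 61 higher and was set aside because it removes members by their outcome. The remaining higher members were pcm1 (2.12), TUBGCP4 (2.2), stil (1.23) and tubgcp3 (1.19), and the lower ones were nde1 (-1.30), cep55l (-0.99) and cep57l1 (-0.99); without any 1 input library or IP replicate 1 none of these 65 was called, without IP replicate 2 there were 10 higher and 3 lower and without IP replicate 3 there were 4 higher and 1 lower.

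Ribosomal protein transcripts were lower in IP, with a median log2 fold change of -1.20. Scaling as the cause was tested with 5 other scalings, under which the list's median came no closer to 0 than -1.17, while the median of all genes moved by at most 0.175. Under-recovery of genes of short genomic span was tested on 984 other genes. Their spans (in assembly GRCz12tu) lay inside the interquartile range of the ribosomal protein genes. Their median was -0.16 (95% bootstrap interval -0.21 to -0.10), which leaves most of the difference unaccounted for. The interval resampled genes, so it leaves out the spread between libraries. A weaker trend with span was present over all genes, from -0.23 in the shortest 1094 genes to 0.25 in the longest 1094. Transcript length was not tested and, like a lower association of these transcripts with Tdrd6a, which input alone cannot separate from background binding, stays open.

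The tdrd6 transcript was higher than input in IP replicates 1 and 3 (3.02-fold and 2.76-fold) and lower in IP replicate 2 (0.495-fold). Low depth of that library was tested first: its 368 reads put the upper 95% exact Poisson bound of this fold at 0.549, below 1. The bound covers counting error only, so other effects of a shallow library stay open. IP replicate 2 standing apart as a whole was then tested by counting genes other than tdrd6, with at least 50 mean reads, in which it lay over 1.5-fold beyond the inputs on the other side from both other IP libraries: 74, against 0 each for IP replicates 1 and 3 (at most 4 when these were thinned to its depth, 100 times). A departure shared by the libraries of replicate 2 was tested with each IP set against the input of its own number: replicate 2 lay over 1.5-fold opposite to both other pairs in 226 genes, against 70 for replicate 1 and 88 for replicate 3, which did not decide it. Input replicate 2 also stood with IP replicate 2 on the second principal component (-52.4 and -61.0, the other libraries between 9.05 and 51.6), so whether the departure belongs to that IP library alone or to both libraries of replicate 2 stays open, and no biological explanation was tested.

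Transcripts with reads in IP and at most 3 in the inputs together were called for 5 genes, DNAH10, stab1l, lrp2b, unc13a and si:dkey-9l20.3, of which 0 were called without input replicate 1, input replicate 3 or IP replicate 1, 1 without input replicate 2, 3 without IP replicate 2 and 4 without IP replicate 3. The transcript of lrp2b had 0 input reads and 48, 19 and 20 reads in IP replicates 1, 2 and 3, at least 12.8-fold higher against a floor of 3 reads per input library, and that of stab1l was at least 9.96-fold higher. Shallower inputs as the cause are argued against by the totals, 1.28 times as many reads in the 3 inputs as in the 3 IP libraries. Read-through from a strongly enriched neighbour was examined by gene position only. Of the 4 genes that could be placed, 0 had such a gene among the 2 nearest on each side (upper 95% exact binomial bound 60.2%), too few to decide. No biological explanation was tested.

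Other splits of the libraries were fitted in the same way. The real split called 838 genes and was the only 1 of 10 splits with as many, the highest other giving 0; with the block it was 1392 against 0, and 1 of the 4 splits that part all pairs had as many. For gene lists, 3 of 10 splits called at least the 6 of the real split, the highest other calling 8. Neither 10 nor 4 splits can give a share under 0.05. Every other split also put both IP and input libraries in each group, so differences between IP and input widened the spread within groups. Few gene calls there follow from that mixing, so the counts do not test whether the real difference arose by chance. Those splits still held unequal numbers of IP libraries on each side, so they give no null for the gene lists either.

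Between IP libraries, the germ plasm transcripts of replicate 3 lay below those of replicate 1 by a median log2 difference of -1.26, and 91 other genes at least 8-fold higher in IP, those with at least 50 mean reads, by -1.22. The medians were 0.90 and 0.18 for replicate 2 against replicate 1, and -1.98 and -1.45 for replicate 3 against replicate 2.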
